A study of Mus musculus with 6 samples.

How the data were processed

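The labels describe RNA immunoprecipitation followed by sequencing from wild-type E14 mouse embryonic stem cells (129/Ola), grown with 15% serum and 1000 U/ml LIF. Per the labels' protocols, cytoplasmic extracts were made by hypotonic lysis, and RNA was taken from the extract or after precipitation with an antibody against Brf1 and Brf2 or with rabbit IgG. The 6 libraries form 3 groups of 2: total RNA, Brf immunoprecipitate and IgG control. RNA was fragmented at 94 C, and TruSeq libraries with fragments near 200 nt were cut from gels as a 350 bp band, per the labels.

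Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 1.1.2, eXpress 1.1.1 and the mm9 build were used. The role and settings of each are not given in the sources used here. The deposited table has the columns of an eXpress output, per the file headers, with 1 model per gene symbol. The authors deposited total and unique read counts as counts, not normalized. They also deposited estimated counts, per the file headers. The total and unique counts are equal in every row, so the table holds no record of reads shared between similar genes. FPKM was deposited by the authors with lower and upper bounds, per the file headers. It was checked that FPKM equals the count divided by the effective length and by the total count, in the usual scaling. One row that names no gene holds 22625281, the sum over the 18312 gene rows, and was left out. Strand handling is not stated in the table, so overlapping and antisense genes cannot be told apart.

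No column names a library, and no group was inferred from values, order or file size. The 9 planned comparisons, which assumed a value for each library, were not run, and no fold change or test between groups was computed. The count columns allow no count model with a single unassigned profile. The depth was 22625281 counts, and the limit for a gene with 0 counts is 3 counts. The share of counts held by a single gene carries a Wilson 95% interval, and other shares carry none.

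The table's symbols were used as given. For sequence properties, 18147 of 18312 symbols (99.1%) were matched to GENCODE M21, directly or through 1 RefSeq synonym. That annotation is on another build than mm9, so no coordinates are printed. Transcript GC was taken from the transcript nearest in length where it lay within 10% of the model length (15454 genes). 3′ untranslated regions were the exon bases past the stop codon, with a minimum of 50 nt (17568 genes), taking the longest per gene. The region was not matched to the transcript model behind the FPKM and can exceed it. For Rps20 the region had 3167 nt and the model 502 nt.

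Before the data were examined, 14 gene lists and 5 marker lists were fixed. The rule for named genes was written for comparisons between groups. The parts that apply here are members of these lists, Zfp36l1, Zfp36l2 and the 5 genes with the highest FPKM. Other genes were named after their values were seen. The value of 1 list member is not reported here. A list's median was ranked among 10000 random lists of the same size matched on model length in 10 bins. The motif difference in log2(FPKM + 1) was tested by 100000 two-sided permutations within 10 bins of 3′ untranslated region length, for genes with at least 1 FPKM. The list ranking and the motif comparison were tested on simulated data, with 100 simulations at each fold and fewer random lists and permutations than above. For the motif comparison of 10078 genes, a difference was called in 4 simulations without a change, in 89 at 1.1-fold and in 100 at 1.25-fold. The simulated motif was placed at random within the length bins, so these runs do not cover a motif that tracks AT content. For the list percentile over 18312 genes, a list ranked in the top 2.5% of random lists in 1 simulation without a change, in 49 at 4-fold and in 92 at 16-fold.

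Alternatives, all chosen after the table was seen, were the model length in place of the effective length, an FPKM threshold of 5, a minimum of 10 counts, and for the motif comparison other regions, motifs, filters, bins and pseudocounts (10 settings in all). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.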

Results

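The study asked which mRNAs are bound by Brf1 and Brf2 in mouse embryonic stem cells. Brf1 (gene Zfp36l1) and Brf2 (gene Zfp36l2) are zinc finger proteins of the ZFP36 family, which bind AU-rich elements in 3′ untranslated regions and recruit mRNA decay enzymes. The labels describe 6 libraries from the E14 line in 3 groups of 2. These were total RNA, RNA immunoprecipitated with an antibody against Brf1 and Brf2, and RNA immunoprecipitated with non-specific rabbit IgG as the background control. One table was analysed here, with 22625281 counts over 18312 genes, 1 transcript model per gene symbol. Nothing in it names a library, so it was assigned to no group, and whether it holds 1 library or a pool is not stated in it.

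The comparison of Brf immunoprecipitate with IgG, which asks which transcripts the antibody enriches, was therefore not made. The comparisons of each immunoprecipitate with total RNA, which ask how far recovery departs from abundance, were not made either. There are no replicates, and each value below is the authors' single value. Intervals on FPKM (fragments scaled to the effective length and the total count) are those in the authors' table. Together with the limits given for counts of 0, they cover counting error only. A level in this table is not a measure of binding or of enrichment. It may not be a measure of expression in the cells either, since the table may hold immunoprecipitated RNA.

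The gene with the highest FPKM was Ptma, which encodes prothymosin alpha, at 4001 FPKM (3978 to 4024). It was followed by the translation elongation factor Eef1a1 at 3461, the cyclophilin Ppia at 3075, the glycolytic enzyme Gapdh at 2729 and the ribosomal protein Rplp1 at 2074. The order depends on the effective length. On the model length Eef1a1 came first at 6547, before Ptma at 4559, and Gapdh at 3576 passed Ppia at 3197. Eef1a1 had the most counts, 265004, which was 1.17% of the total (Wilson 95% interval 1.167 to 1.176). All 46 measured cytosolic ribosomal protein genes had at least 196 FPKM, with a median of 803 (1253 on the model length), and together they held 5.20% of the counts. The 100 genes with the most counts held 19.97% of them. Of all genes, 10257 (56.0%) had at least 1 FPKM and 3844 (20.99%) had no count. The median limit that a count of 0 allows, 3 counts, was 0.125 FPKM.

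Of the 32 measured members of the naive pluripotency list, 31 had at least 1 FPKM, with a median of 29.7. The core transcription factors were among the abundant ones. Pou5f1 had 605 FPKM (598 to 613, 28145 counts), Nanog 187 (183 to 191, 9136 counts) and Sox2 179 (176 to 182, 14451 counts). The Nodal co-receptor Tdgf1 had 466 FPKM, the RNA-binding protein Lin28a 186 and Zfp42 158. On the model length Sox2 (260) was above Nanog (183), and Zfp42 (281) was above Lin28a (208). Other factors of the naive network were lower, with Esrrb at 40.6, Klf2 at 38.6, Klf4 at 13.9, Tbx3 at 2.21 and Prdm14 at 2.00. The list median lay above those of all 10000 random lists of the same size matched on model length (percentile 100), which describes this table and is not a test across samples. The member under 1 FPKM was Dppa5a, listed at 0.683 FPKM (0.674 to 0.692) with 21876 counts, the 107th highest count. Its model is 639 nt long and its effective length in the table is 1415960. Computed on the model length, its level was 1513 FPKM. Rex2 went the other way, from 460 FPKM on the effective length to 108 on the model length.

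**Figure D1:**
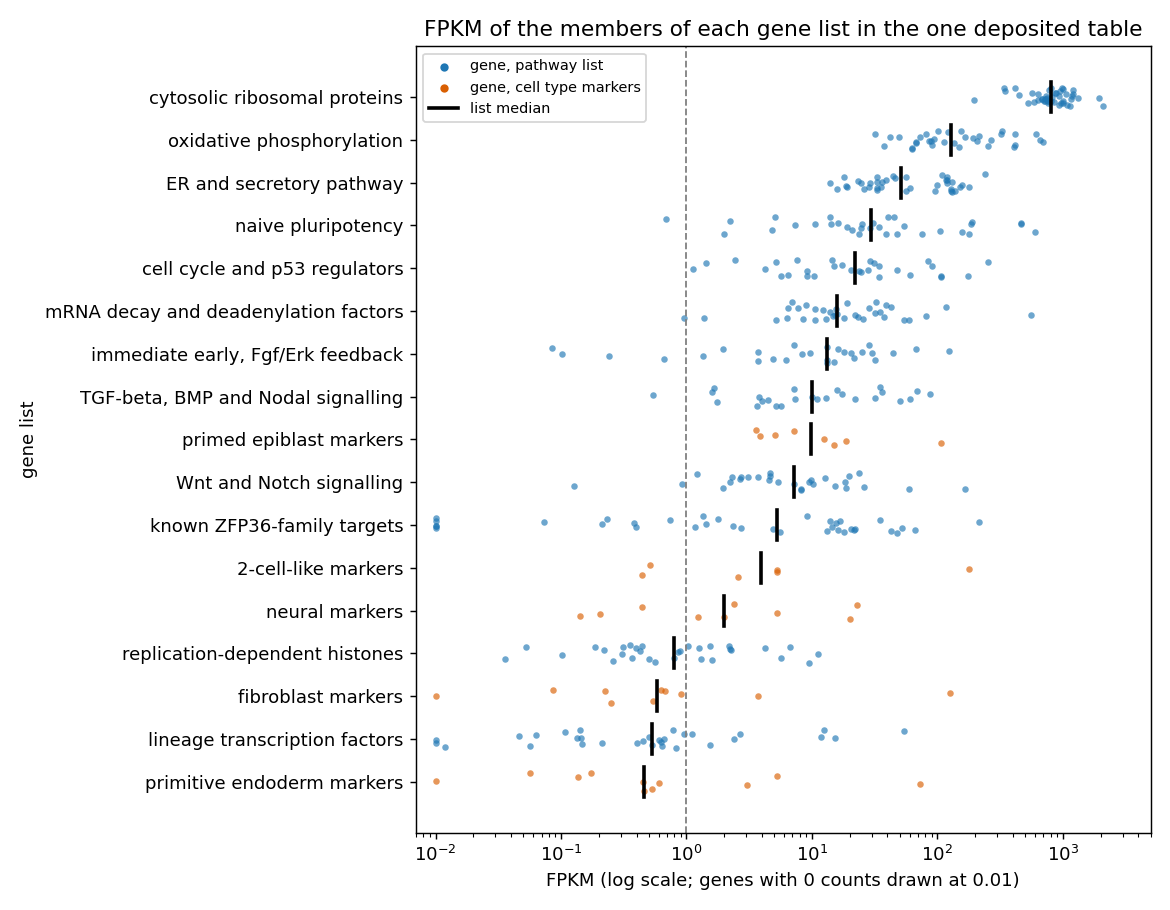
FPKM of each measured member of the lists fixed before the data were examined, on a log axis. Each point is a gene, black bars are list medians, the dashed line marks 1 FPKM, and genes with 0 counts are drawn at 0.01. The ribosomal protein list has the highest median, 803 FPKM, and the primitive endoderm markers the lowest, 0.456; the lists with 1 or no measured member are not drawn.

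Lineage transcription factors were mostly low. Of 31 measured, 8 had at least 1 FPKM and the list median was 0.535, at percentile 2.55 among random lists (1.93 on the model length). Among these 8, the mesoderm factor T had 15.4 FPKM, Otx2 12.4 and Zic2 11.9. Gsc and Neurog2 had no counts. Markers of other cell types were recorded because the labels do not describe the purity of the cultures. Their levels cannot settle that purity, because the group behind the table is not known. Of 10 fibroblast markers, 2 had at least 1 FPKM, Tagln at 125 and Thy1 at 3.74. Of 11 primitive endoderm markers, 3 did, with Sparc at 73.2, Col4a1 at 5.24 and Dab2 at 3.05. All 8 primed epiblast markers did, with a median of 9.85 and Dnmt3b highest at 106. Of 6 markers of 2-cell-like cells, 4 did. These were Zscan4f at 5.28, Zscan4c at 5.28, Zscan4d at 2.58 and Eif1a, a general translation initiation factor, at 177. Of 9 neural markers, 6 did, with a median of 1.99 (3.14 on the model length). Tubb3 had 22.9 FPKM and Nes 20.1, and on the model length Nes was the higher, at 39.6 against 36.5.

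The transcripts of the antibody's own targets were present. Zfp36l1 had 42.7 FPKM (41.1 to 44.3, 2749 counts) and Zfp36l2 had 22.2 (21.2 to 23.1, 2180 counts). The intervals do not overlap, and on the model length Zfp36l1 was again the higher, at 40.7 against 27.3. Zfp36 had 17.9 FPKM and Zfp36l3 had 0.961. Of 35 measured mRNA decay and deadenylation factors, 34 had at least 1 FPKM, with a median of 15.9. The poly(A)-binding protein Pabpc1 was highest at 562, and the deadenylase scaffold Cnot1 had 59.5.

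Of 36 measured textbook targets of the ZFP36 family, a list drawn mostly from work on Zfp36 in other cell types, 25 had at least 1 FPKM. The median was 5.23, at percentile 95.5 among random lists, and on the model length it was 8.59, at percentile 98.3. Mcl1, an anti-apoptotic factor, was highest at 215 FPKM. Pim1 had 66.8, Hif1a 52.6, Ccnd1 48.1, Myc 21.7 and Ier3 13.1. Tnf had 0.398 FPKM, and Csf2, Il3, Il6, Ccl2 and the Notch ligand Dll4 had 0 counts. The limits that 0 counts allow were 0.142 FPKM for Csf2, 0.185 for Il3, 0.186 for Il6, 0.230 for Ccl2 and 0.0256 for Dll4.

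Among signalling lists, 24 of 28 measured immediate early and Fgf/Erk feedback genes had at least 1 FPKM (median 13.1, percentile 99.9). Etv5 was highest at 123, Spry2 had 67.5 and Fos 1.34. For TGF-beta, BMP and Nodal signalling, 24 of 25 did (median 9.94, percentile 99.0), with Lefty1 at 87.9, Skil at 68.8 and Tgfbr2 at 0.540. For Wnt and Notch signalling, 27 of 29 did (median 7.25, percentile 94.3), with the Wnt effector Ctnnb1 highest at 167. Of these 27, 16 had at least 5 FPKM. All 30 measured cell cycle and p53 regulators had at least 1 FPKM (median 22.2), with Ccnb1 at 253 and Trp53 at 175. All 34 oxidative phosphorylation genes and all 38 endoplasmic reticulum and secretory pathway genes did too, with medians of 129 and 51.1. Of 31 replication-dependent histone genes, 13 did (median 0.800, percentile 89.4), and on the model length 16 did (median 1.27, percentile 91.5). The highest histone gene was Hist1h2ad at 11.1. One nuclear noncoding RNA of 16 listed was measured, Snhg11 at 10.96 FPKM. None of the 24 structured noncoding RNAs on the list was found under its listed symbol.

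The planned question about AU-rich motifs, whether TATTTAT in the 3′ untranslated region is commoner among enriched transcripts, could not be put without groups. Levels of genes with and without the motif were compared in its place, a choice made after the table had been seen. Among 10078 genes with at least 1 FPKM and an annotated 3′ untranslated region, 3089 had the motif, with a median of 9.18 FPKM, and 6989 lacked it, with a median of 10.03. Zfp36l1 and Zfp36l2 each had 3 sites, Nanog had 1 and Pou5f1 none. Within bins of 3′ untranslated region length, the mean of log2(FPKM + 1) with the motif minus that without was 0.01 (permutation SD 0.04, two-sided permutation p = 0.71 across genes, 0.79 after Benjamini-Hochberg adjustment over the 10 settings tried). The sign and the call changed between those settings, which include other motifs, though no positive difference was called for TATTTAT itself. Matched on AT content as well, the difference was -0.24 (p = 1e-05, the smallest that the permutations can give). Genes are not independent replicates. Motif and region length can belong to another transcript than the model behind the FPKM, since the longest region per gene was used.

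**Figure D2:**
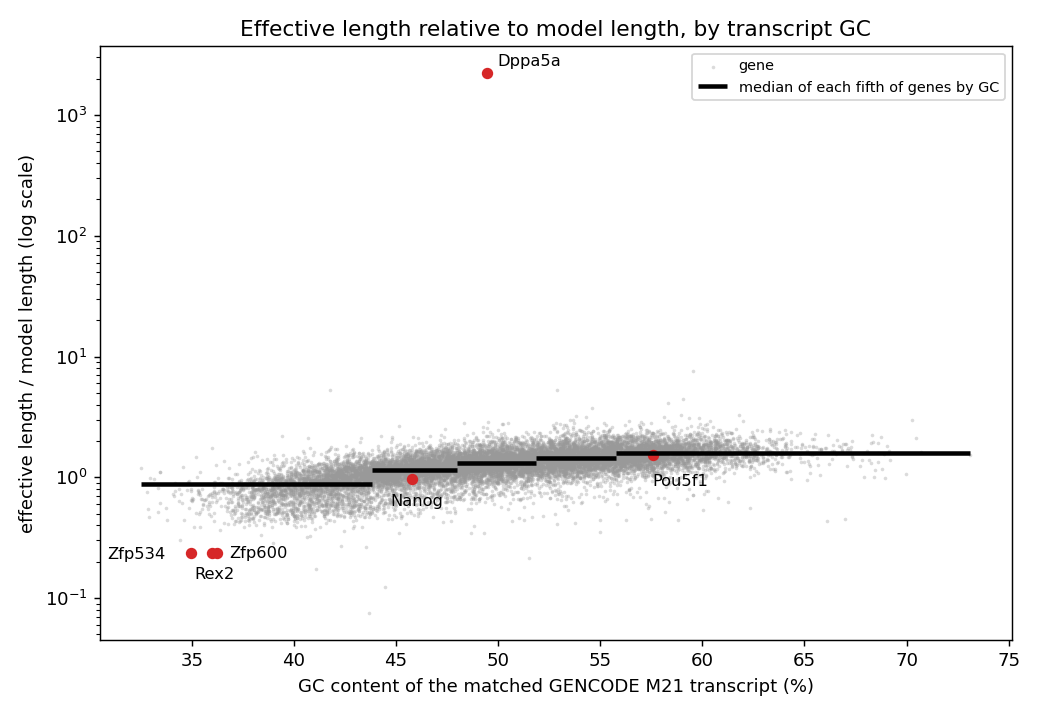
Effective length divided by model length (log axis) against the GC content of the matched reference transcript, for 15454 genes. Grey points are genes, black bars are medians of 5 equal groups of the genes by GC, and named genes are in red. The medians rise from 0.883 to 1.58, Dppa5a lies at 2216, and Rex2, Zfp534 and Zfp600 lie near 0.235.

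FPKM in the table depends on the effective length, which exceeded the model length by a median factor of 1.27 (5th to 95th percentile 0.640 to 1.94). Of genes with at least 1 FPKM, 144 moved by more than 2-fold beyond the median shift when the model length was used. Among them were 3 zinc finger genes with a ratio under 0.25 and at least 500 counts, singled out after their values were seen. These were Rex2, Zfp534 and Zfp600, and on the model length Zfp534 went from 1410 to 331 FPKM and Zfp600 from 475 to 112.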

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

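All settings here were chosen after the table was seen. No paired analysis was possible because the table's columns carry no replicate number or group. For the same reason the alternatives listed before the data were examined (other tests and pseudocounts for the group comparisons, other filters, leaving out each library, the replicate block) were not run.

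Of 20 list counts, 15 stayed within 1.5 times under the model length, a threshold of 5 FPKM and a minimum of 10 counts. At a threshold of 5, the counts were 4 lineage transcription factors, 16 Wnt and Notch genes, 4 histone genes, 1 fibroblast marker and 3 neural markers. With the model length, 4 fibroblast markers had at least 1 FPKM. Of 472 named genes, 334 were higher with the model length beyond their interval, 48 lower and 90 within it.

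The motif difference had no stable sign across settings and motifs. With two-sided permutation p values, it was 0.40 for ATTTA (p = 1e-05), -0.22 for TTATTTATT (p = 0.00017), -0.10 without an FPKM filter (p = 0.008), -0.0905 at 5 FPKM or more (p = 0.015), -0.0746 with the model length (p = 0.053), -0.24 matched on AT content as well (p = 1e-05), 0.03 with the shortest region (p = 0.48), 0.03 with a pseudocount of 0.1 (p = 0.55) and -0.0026 with a pseudocount of 4 (p = 0.93). Of the values with p under 0.05, only that of ATTTA, another motif, was positive. ATTTA and TTATTTATT were matched on length and not on AT content, so their values cannot be set against the -0.24. The positive values for TATTTAT itself had permutation p of 0.48 or more. The cause was not tested for the changes between filters and motifs. Genes with few counts have wide intervals, and a single profile gives no spread between samples.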

Other observations

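The glycolysis and chromatin lists and these tests were chosen after the results were seen: the effective length assigned to Dppa5a, short models, the effective length correction before matching, and the order of bases in TATTTAT. All 19 measured glycolysis genes had at least 1 FPKM, with a median of 126, and together they held 2.30% of the counts. After Gapdh, the highest were Pkm at 954 FPKM, Eno1 at 910 and Ldha at 698, although on the model length Eno1 (2059) was above Pkm (1968). The glucose transporters Slc2a3 and Slc2a1 had 382 and 217. Hk2 had 42.6 FPKM and Hk1 4.20. All 25 measured genes for DNA methylation and repressive chromatin had at least 1 FPKM, with a median of 53.6 (82.4 on the model length). Trim28, a co-repressor of KRAB zinc finger proteins, was highest at 251, and Hdac1 had 154. Dnmt3b had 106 FPKM against 18.3 for Dnmt3a, and Tet1 had 31.1 against 7.99 for Tet2 and 2.04 for Tet3. Both lists were drawn up after the abundant genes of this table were seen, so their rank among random lists (percentile 100 for each) is not independent evidence.

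Dppa5a, a pluripotency marker, was listed at 0.683 FPKM with 21876 counts. The table argues against GC content, since the highest ratio of effective to model length among 1594 other transcripts within 1 percentage point of its GC was 2.85, against 2216 for Dppa5a. The low value follows by arithmetic from its effective length, and its rank of 34 among all genes on the model length follows from its count, so neither tests why that effective length was assigned. Dppa5a has near-identical copies in the genome. Reads lost to them would lower its count, but that count was the 107th highest. Such a loss is therefore not the source of the low FPKM. Whether shared reads affected the count or the effective length in another way stays open, because total and unique counts differ in 0% of rows. No biological explanation was tested, since the table has no group.

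Effective lengths departed from model lengths across the table. The ratio rose with transcript GC across genes (Spearman rho 0.678), and the median of longer models was 1.41 times that of the 252 models under 500 nt. Both are consistent with sequence and fragment length corrections in the authors' quantification, which the table does not record. Neither accounts for Dppa5a. No biological explanation was tested.

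Among genes with at least 1 FPKM, those with TATTTAT in the 3′ untranslated region had lower FPKM before matching (difference -0.19 in log2). Without that filter, across 17568 genes, the unmatched difference was 0.04, so its sign depends on the filter. At 1 FPKM or more, matching on length left a difference of 0.01 (permutation p = 0.71). Adding AT content brought back a negative one (permutation p = 1e-05, the smallest possible), so the prediction for AT content, no difference left, failed. It moved the difference from 0.01 to -0.24, below the unmatched -0.19. Within length bins, this argues against AT content as the source of a lower FPKM. No setting matched on AT content alone, so its part without length is not known. Length stays open as a source of the unmatched difference. The effective length correction is not the source of the unmatched difference at 1 FPKM or more, which was larger with the model length (-0.34). The test for that correction within length bins was set down after the table was seen but before its value was known. Its result (permutation p = 0.053) decides nothing, because no difference was detected there with the effective length either. Matched on length alone, the 21 arrangements of the bases of TATTTAT, which share 1 composition, ran from 0.01 for TATTTAT, the lowest, to 0.41 for TTTTTAA. Matched on length and AT content, they ran from -0.25 for TATTATT (permutation SD 0.05) to 0.13 for TTTTTAA (SD 0.06). The composition of the motif alone therefore does not give the value of TATTTAT, -0.24 (SD 0.04). The gaps between arrangements were not tested. TATTTAT is not shown to differ from TATTATT, ATTATTT (-0.23) and TTATTAT (-0.22), whose values lie within 1 SD of its own. That SD is the spread of a single arrangement under permutation, not of the gap between arrangements. Arrangements further off, such as TTATTTA (-0.19) and ATTTATT (-0.17), are therefore not shown to differ from TATTTAT. No biological explanation was tested.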
